A study of Danio rerio with 30 samples.

How the data were processed

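Polyadenylated RNA from adult zebrafish (Danio rerio) retinas was sequenced in 30 libraries, which fall into 10 groups of 3. The labels place 12 libraries in a needle poke experiment (4 groups, all wild type) and 18 in an NMDA experiment (6 groups, wild type and csf1ra or csf1rb mutants). Titles of the libraries carry the letters MG, the usual short form of Müller glia, but the extraction notes describe whole retinas triturated in TRIzol and name no sorting of cells. The values are therefore read as levels in whole retina, but sorted glia are not excluded. Had cells been sorted, the lists of other cell types would not describe the whole retina. The labels do not state whether the 3 libraries of a group come from separate fish, so the p-values measure only the spread between libraries.

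Per the submitters' processing notes, reads passed through cutadapt 4.8, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 with the genome build GRCz11, without stated parameters or annotation release. The deposited tables, 1 per experiment, hold expected counts per gene as whole numbers that were not scaled between libraries, and the replicates were not pooled. The whole numbers are taken as rounded estimates, because RSEM estimates counts. The table of the needle poke experiment has 21 columns, of which 12 match samples by library name and 9 match no sample and were not used. Each table lists 32524 entries. Of these, 32520 are Ensembl genes and 4 are reporter transgenes (egfp, cre, mcherry and tdtomato), which were left out of the fits and of the gene and list tests. Only egfp was compared, in 1 separate permutation test. Symbols came from a table that pairs Ensembl IDs with names and covers 29201 of the IDs, 12592 of them with symbols in capitals. A symbol that belongs to more than 1 gene is printed with its Ensembl ID. Chromosome positions of genes were not used, except in 1 test that used positions by symbol.

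Total counts over genes were 38933511 to 92198888 per library in the needle poke experiment and 22849708 to 41622168 in the NMDA experiment. The files hold no molecular identifiers, so the floors below cover counting error only. No 2 libraries of a group were copies of each other, since the lowest chi-square per degree of freedom between any 2 of a group was 7.97. Libraries of different groups were not compared this way.

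Each experiment was fitted once, with all its libraries, by edgeR 4.0.16 (quasi-likelihood F test, robust, two-sided) in R 4.3.3 with limma 3.58.1. The model had 1 mean per group and TMM scaling. The 2 experiments were never fitted together, because only 1 holds drugs and only the other holds mutants. Genes with low counts were removed with filterByExpr by group, which kept 21334 of the 25975 genes with any count in the needle poke experiment and 20254 of 26728 in the NMDA experiment. The genes kept held 99.98% and 99.97% of the counts. The common biological coefficient of variation was 0.292 and 0.171. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene is called at an adjusted p under 0.05. Rises, falls, higher and lower are used only for called genes unless stated. There were 14 comparisons, of which 12 set one group against another and 2 are interactions that test whether the injury change of a mutant differs from that of the wild type. Gene levels are CPM, counts scaled by edgeR to a common library size with the TMM factors, given as mean ± SD with n = 3, and changes are log2 fold changes of the fit. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, only CPM values are given, except for 2 interaction values (stm and dscc1), which stand beside their CPM.

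On simulated counts with 200 genes changed, the test of PLX3397 against DMSO recovered 7.4%, 50% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 false calls. The test of csf1ra mutants against wild type after NMDA recovered 14.7%, 74.2% and 95.5%, with 5 false calls. With no gene changed, both gave 0 false calls. Changes below 2-fold are therefore often missed at this depth and number of libraries.

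The comparisons, the tests, 34 gene lists of retinal cell types and processes, the alternatives and the rule for naming genes were fixed before the data were examined. The lists hold 1203 genes. Because many symbols in the table are in capitals, matching was widened after the tables were seen and before any group comparison was. Of the list genes, 512 matched as written, 372 in another letter case, 20 through a synonym and 238 without the paralog letter, which leaves 61 unmatched. Results with the first 2 kinds alone are among the alternatives. Of 1042 list genes tested in the NMDA experiment, 53 are in more than 1 list and 777 reached 1 CPM in the wild-type uninjured retina. Of 1084 tested in the needle poke experiment, 844 reached it in the untreated uninjured retina. A list is therefore a set of genes linked with a cell type or process and not a measure of cell number.

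Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the 34 lists of a comparison. Counts of called members are given over all genes and adjusted over the list alone. The same test with the correlation estimated from the residuals, and fry, were run beside it. Fry asks whether the genes of a list move one way on balance, and its mixed form whether they change in either direction, and neither compares a list with other genes. The sign of the median, the mean and the camera test did not differ in any called list. Gene sets called by injury in one experiment were tested in comparisons of the other, with which they share no library. Agreement between comparisons is Pearson's r and the covariance over genes, which are not independent replicates. Where comparisons share controls, unchanged groups against the same controls were simulated and are given beside.

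The rule for named genes takes csf1ra and csf1rb in every comparison, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 CPM. These also needed a symbol that is not a clone or placeholder name and, outside the interactions, all libraries of one group above all of the other. Chance alone gives that separation in 10% of genes for 3 libraries against 3. A largest rise or fall in the text is the largest under these conditions. The rule adds up to 4 members with the smallest p from each called list. The text gives fewer, taken in this order for the largest changes and chosen for their known role, after their values were seen, among the members of lists. Near-identical paralogs (opn1lw1 and opn1lw2, opn1mw1 and opn1mw2, her4.3 and her4.4, fbxo44.9 and fbxo44.10, hsp70.1 and hspa1b, cd74a and cd74b, znf1179 and hbaa1 with their relatives) share reads, so the split of their counts is uncertain.

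The alternatives were RLE factors, 2 other low-count filters (none, or 1 CPM in 3 libraries), the replicate number as a block, only the groups compared in the fit, DESeq2 1.42.0, each library left out in turn, the estimated correlation, fry, genes of at least 10 CPM for agreement, and the 200 genes with the smallest p for the injury sets. Chosen after seeing the data were list genes matched by symbol alone and a fit without 4 libraries of the needle poke experiment that stand apart on the third principal component (poke DMSO replicate 3, poke PLX3397 replicate 2, poke ZVAD-fmk replicate 1 and untreated uninjured replicate 2). Other splits of the libraries were refitted, all 10 for each pair of groups and 60 of 200 for each interaction. Simulated values and the 60 splits depend on the random draw, which was fixed by a seed. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.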

Results

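Levels of retinal transcripts were measured in 30 libraries of adult zebrafish, in 10 groups of 3. In the needle poke experiment, wild-type retinas were untreated and uninjured, or were stabbed with a needle while the fish swam in DMSO (the solvent control), PLX3397 or ZVAD-fmk. PLX3397 (pexidartinib) inhibits the colony-stimulating factor 1 receptor, on which microglia and macrophages depend, and ZVAD-fmk inhibits caspases, the proteases of apoptosis. In the NMDA experiment, wild-type fish and mutants in csf1ra or csf1rb, the paralogs of that receptor in zebrafish, had uninjured retinas or retinas injured by NMDA, an excitotoxin injected into the eye. Injured retinas were taken 2 days after injury. Total counts ranged from 38933511 to 92198888 per library in the needle poke experiment and from 22849708 to 41622168 in the NMDA experiment. The first principal component held 55.7% of the variance in the needle poke experiment and 84.2% in the NMDA experiment. On the third component of the needle poke experiment (9.9%), poke DMSO replicate 3, poke PLX3397 replicate 2, poke ZVAD-fmk replicate 1 and untreated uninjured replicate 2 each stood apart from the others of their group. The mean level of the microglia and macrophage list was 4.05 log2 CPM in poke DMSO replicate 3, against 1.95 and 1.93 in the other two.

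The receptor genes were compared in every group, since the drug and the mutants target their products. In the needle poke experiment, csf1ra (ENSDARG00000102986) stood at 5.96 ± 3.36 CPM in untreated uninjured retinas, 17.1 ± 14.7 in poke DMSO, 5.41 ± 1.71 in poke PLX3397 and 13.2 ± 1.13 in poke ZVAD-fmk (SD, n = 3). It was called higher after poke (log2 fold change 1.51, adjusted p = 0.039) and lower with PLX3397 (-1.66, adjusted p = 0.024). Without poke DMSO replicate 3 neither was called (0.55 and -0.70), and each call also ended in 5 other settings. Leaving out untreated uninjured replicate 2 raised the former to 2.11. The difference between ZVAD-fmk and DMSO (-0.37, adjusted p = 0.66) was 0.60 without poke DMSO replicate 3, without a call either way. The paralog csf1rb (ENSDARG00000053624) was scarce, at 0.703 ± 0.319, 1.3 ± 0.996, 0.288 ± 0.123 and 0.618 ± 0.0189 CPM in the same order. Its fall with PLX3397 (-2.16, adjusted p = 0.034) ended in 8 of 12 other settings, among them leaving out any 1 of 5 libraries (-1.46 without poke DMSO replicate 3).

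In the NMDA experiment, csf1ra was at 4.15 ± 0.211 CPM in uninjured wild-type retinas and at 0.245 ± 0.0778 in uninjured csf1ra mutants (log2 fold change -4.04, adjusted p = 6.8e-08 by edgeR). After NMDA the values were 6.98 ± 0.433 in wild type and 1.39 ± 0.1 in csf1ra mutants (-2.32, adjusted p = 1.7e-06). The csf1rb mutants also had less csf1ra, with 1.35 ± 0.466 CPM uninjured (-1.62, adjusted p = 3.7e-05) and 3.63 ± 0.445 after NMDA (-0.94, adjusted p = 0.002). NMDA raised csf1ra in wild type (0.75, adjusted p = 0.0025), in csf1ra mutants (2.47, adjusted p = 5.4e-07) and in csf1rb mutants (1.43, adjusted p = 1.2e-05). The csf1rb gene had only 2 to 46 counts per group. Its level was 0.595 ± 0.238 CPM in uninjured wild type, 0.0977 ± 0.0707 in uninjured csf1ra mutants and 0.17 ± 0.174 in uninjured csf1rb mutants. Both mutant differences passed the test (-2.53, adjusted p = 0.014, and -1.82, adjusted p = 0.029). The former ended without csf1ra mutant uninjured replicate 5 (-2.15) or wild-type uninjured replicate 3 (-2.26) and was -3.26 without csf1ra mutant uninjured replicate 4, and the latter without csf1rb mutant uninjured replicate 1 (-1.53) or 3 (-1.35) or wild-type uninjured replicate 1 (-1.74) or 3 (-1.55) and was -3.05 without csf1rb mutant uninjured replicate 2. After NMDA, csf1rb was at 0.328 ± 0.054 CPM in wild type, 0.105 ± 0.0356 in csf1ra mutants (-1.59, adjusted p = 0.097) and 0.0197 ± 0.018 in csf1rb mutants (adjusted p = 0.0043), the last with 2 counts over the group.

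**Figure D1:**
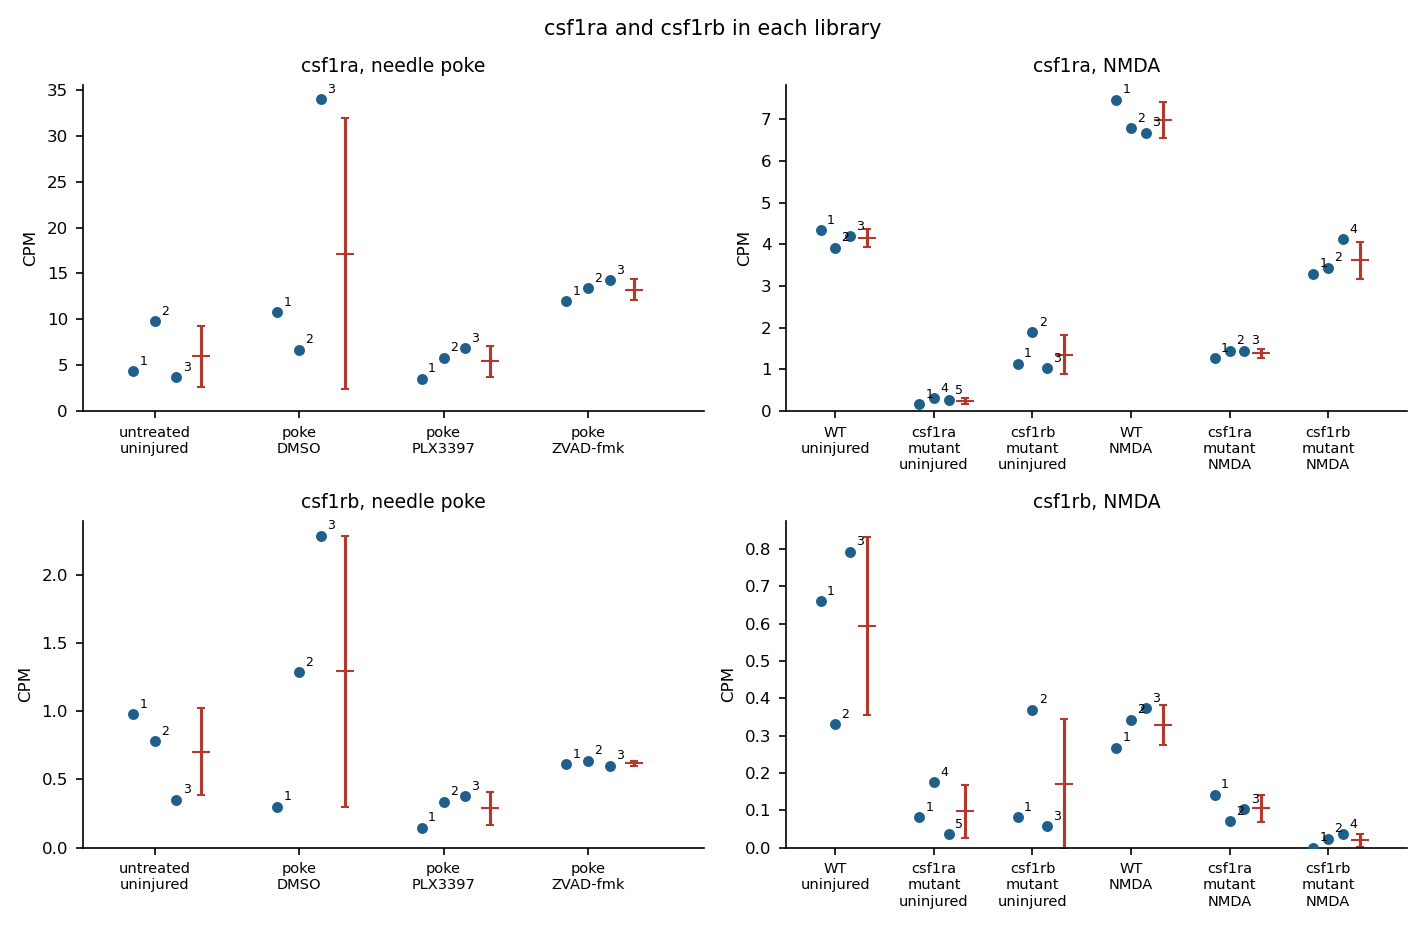
Levels of csf1ra and csf1rb (vertical axis, CPM) in each library of the 4 groups of the needle poke experiment and the 6 groups of the NMDA experiment. Points are libraries with their replicate number and bars are the mean and SD. In uninjured csf1ra mutants csf1ra lay at 0.245 CPM on average, against 4.15 in wild type.

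Across the 14 comparisons, 191 list tests passed with the preset correlation between genes and 13 passed with an estimated one. Those 13 are DNA replication and S phase after poke and after NMDA in all 3 genotypes, mitosis and cytokinesis in the comparisons of poke and of either drug, proneural and neurogenic genes in the same 3 comparisons, and microglia and macrophages in csf1ra mutants in both states and in csf1rb mutants after NMDA. Lens crystallins (smallest adjusted p = 0.062), lymphocytes (0.32), necroptosis and pyroptosis (0.06), surface epithelium (0.12), and xanthophores and iridophores (0.41) passed in no comparison.

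**Figure D2:**
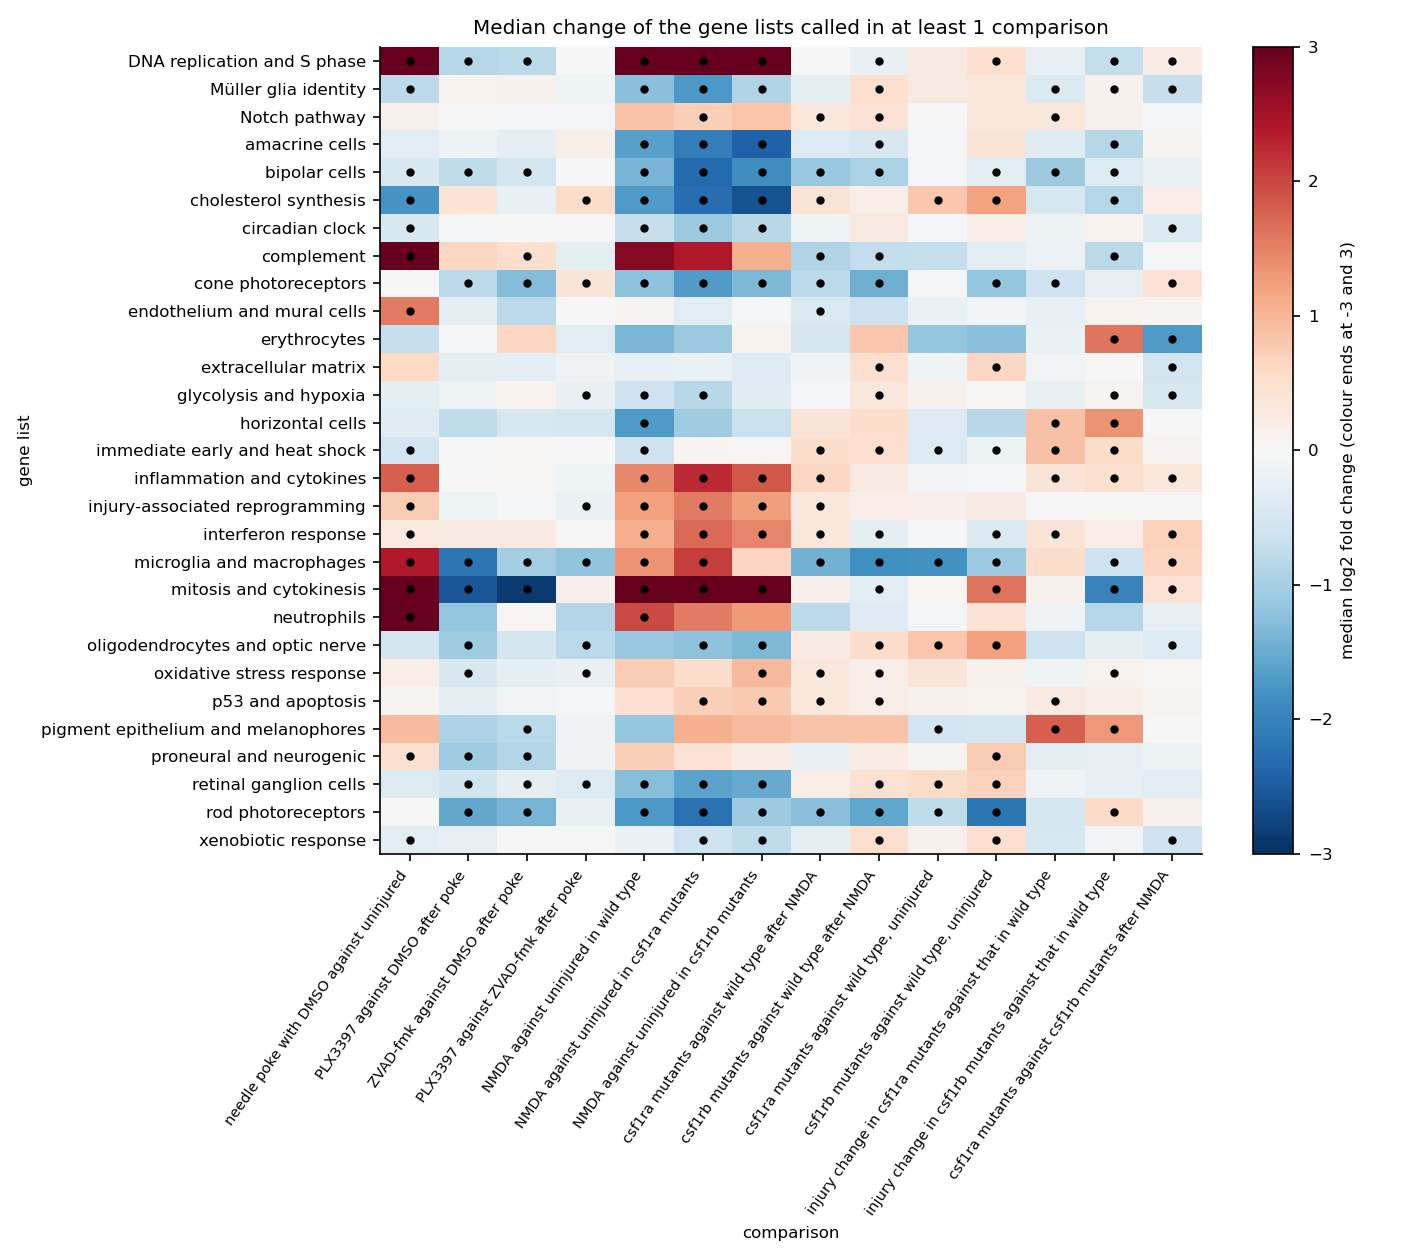
Median log2 fold change of the gene lists that passed the camera test in at least 1 comparison (vertical axis, lists; horizontal axis, comparisons; colour, median, ending at -3 and 3). Dots mark list tests with adjusted p under 0.05 at the preset correlation. The mitosis and cytokinesis list has medians of 4.59 after poke, -2.57 with PLX3397 and -2.87 with ZVAD-fmk.

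Needle poke with DMSO against untreated uninjured retinas shows how the wild-type retina differed 2 days after mechanical injury. Injury and immersion in DMSO came together, so their effects cannot be separated. Of 21334 genes, edgeR with Benjamini-Hochberg adjustment called 3888 higher and 2856 lower after poke. Genes of dividing cells rose. The proliferation marker mki67 went from 7.03 ± 0.404 to 218 ± 18.2 CPM (log2 fold change 4.96, adjusted p = 8.3e-10) and RRM2 (ENSDARG00000078069), which makes deoxynucleotides, from 9.66 ± 1.23 to 259 ± 25.1 CPM (4.74, adjusted p = 3.2e-09). Of 87 mitosis and cytokinesis genes, 84 rose, 0 fell and 3 were not called (84 and 1 adjusted over the list alone), with a median of 4.59 (camera adjusted p = 1.7e-136, 0.0017 with an estimated correlation). Of 71 DNA replication genes, 70 rose and 1 was not called (70 adjusted over the list alone), with a median of 3.49 (adjusted p = 9.2e-134, 0.017 with an estimated correlation).

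Some neurogenic genes also rose after poke. The largest rises were in cart4, a neuropeptide gene with no counts in untreated retinas and 14.3 ± 5.02 CPM after poke (at least 615-fold higher, adjusted p = 5.2e-08), and in clcf1, a cytokine of the interleukin 6 family (58.9 ± 2.63 against 0.00904 ± 0.0157 CPM, 1 count over the untreated group, adjusted p = 3.5e-09). The matrix protease mmp9 reached 781 ± 151 CPM from 0.788 ± 0.0801 (9.96, adjusted p = 8.5e-10). The Notch ligand gene dlc rose (4.46, adjusted p = 6.5e-08) and the neurogenic factor gene foxn4 reached 42.1 ± 4.35 from 3.04 ± 0.526 CPM (3.80, adjusted p = 1.3e-08). Of 36 proneural and neurogenic genes, 14 rose, 4 fell and 18 were not called (16 and 4 adjusted over the list alone), with a median of 0.47 (adjusted p = 6.0e-04, 0.047 with an estimated correlation). Of 64 genes of injury-associated reprogramming, 32 rose, 5 fell and 27 were not called (32 and 10 adjusted over the list alone), with a median of 0.76 (adjusted p = 6.3e-10, 0.32 with an estimated correlation).

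Immune lists were higher after poke. Of 62 microglia and macrophage genes, 41 rose, 2 fell and 19 were not called (45 and 2 adjusted over the list alone), with a median of 2.4 (adjusted p = 1.5e-05, 0.76 with an estimated correlation). Without poke DMSO replicate 3 that median was 1.08, still past the test. Of 22 complement genes, 13 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 3.33, or 3.02 with genes absent from a group at their bound (adjusted p = 4.5e-08, 0.32 with an estimated correlation, median 2.35 without that library). The complement gene c7b went from 21.6 ± 2.73 to 2360 ± 491 CPM (6.78, adjusted p = 1.6e-08). Inflammation and cytokines had a median of 1.79 (adjusted p = 2.3e-05, 0.69 with an estimated correlation), which was 0.64 without that library. Neutrophil genes had a median of 3.30 (adjusted p = 0.013, 0.69 with an estimated correlation), which was 1.74 without it, and did not pass without the 4 libraries that stand apart (1.91). The endothelium and mural cell list, at 1.55 (adjusted p = 0.016, 0.76 with an estimated correlation), did not pass without it (0.71, adjusted p = 0.075). The interferon response list was at 0.29 (adjusted p = 0.0045, 0.69 with an estimated correlation) and did not pass without those 4 (0.20).

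Genes of sterol synthesis and some of Müller glia fell after poke. Squalene epoxidase, SQLE (ENSDARG00000079946), fell from 116 ± 51 to 9.4 ± 0.722 CPM (-3.63, adjusted p = 1.1e-05). The oxidase gene nox1 (-3.82, adjusted p = 4.7e-04) and tnks1bp1, which encodes a tankyrase-binding protein, (-3.69, adjusted p = 0.0012) had the largest falls, at -4.53 and -4.32 without the 4 libraries that stand apart. Of 27 cholesterol synthesis genes, 0 rose, 21 fell and 6 were not called (0 and 22 adjusted over the list alone), with a median of -1.77 (adjusted p = 3.3e-17, 0.25 with an estimated correlation). Of 46 Müller glia identity genes, 6 rose, 21 fell and 19 were not called (7 and 24 adjusted over the list alone), with a median of -0.78 (adjusted p = 1.5e-05, 0.69 with an estimated correlation). In that list cav2, a caveolin, fell from 111 ± 29.6 to 33.1 ± 1.45 CPM (-1.75, adjusted p = 2.5e-06). Lower medians also passed for bipolar cells (-0.45, adjusted p = 0.0085, 0.76 with an estimated correlation), immediate early and heat shock genes (-0.58, adjusted p = 0.01, 0.77), the circadian clock (-0.46, adjusted p = 0.013, 0.69) and xenobiotic response (-0.35, adjusted p = 0.024, 0.69). The last did not pass without poke DMSO replicate 1 (-0.47) or 2 (-0.44) or untreated uninjured replicate 2 (-0.29).

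PLX3397 against DMSO after poke asks which injury levels change when the receptor is inhibited. Of 21334 genes, edgeR called 3511 higher and 3786 lower with PLX3397. Genes of dividing cells were lower. The spindle gene nusap1 fell from 53.7 ± 2.59 to 1.5 ± 0.262 CPM (-5.15, adjusted p = 6.8e-08) and tpx2, which builds the spindle, from 91.5 ± 1.68 to 4.98 ± 0.579 CPM (-4.20, adjusted p = 5.2e-09). Of 87 mitosis and cytokinesis genes, 1 rose, 84 fell and 2 were not called (1 and 85 adjusted over the list alone), with a median of -2.57 (adjusted p = 1.5e-93, 7.6e-04 with an estimated correlation). Of 71 DNA replication genes, 1 rose, 49 fell and 21 were not called (1 and 53 adjusted over the list alone), with a median of -0.85 (adjusted p = 2.1e-15, 0.64 with an estimated correlation). Of 36 proneural and neurogenic genes, 1 rose, 21 fell and 14 were not called (1 and 23 adjusted over the list alone), with a median of -1.07 (adjusted p = 2.5e-10, 9.9e-04 with an estimated correlation). Among them the tubulin gene tubb5 of young neurons fell from 289 ± 25.2 to 68.4 ± 10.7 CPM (-2.08, adjusted p = 1.0e-06).

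Microglial and photoreceptor genes were lower with PLX3397 as well. The chemokine gene ccl34b.1 (9.88 ± 9.75 to 0.0846 ± 0.0742 CPM, -6.84, adjusted p = 8.6e-05) and spp1, which encodes osteopontin (4.52 ± 4.43 to 0.0694 ± 0.062, -6.02, adjusted p = 0.0011), had the largest falls. They were smaller without some libraries, ccl34b.1 at -5.04 without the 4 that stand apart and spp1 at -4.81 without poke DMSO replicate 3. Of 62 microglia and macrophage genes, 3 rose, 37 fell and 22 were not called (3 and 41 adjusted over the list alone), with a median of -2.19 (adjusted p = 3.4e-06, 0.78 with an estimated correlation). Without that library the median was -0.91, still past the test. Of 29 rod genes, 0 rose, 25 fell and 4 were not called (0 and 25 adjusted over the list alone), with a median of -1.53 (adjusted p = 1.6e-15, 0.3 with an estimated correlation). The rod transducin gene gnat1 fell from 857 ± 62.3 to 166 ± 72.7 CPM (-2.37, adjusted p = 3.9e-05). Of 34 cone genes, 0 rose, 22 fell and 12 were not called (0 and 24 adjusted over the list alone), with a median of -0.82 (adjusted p = 7.8e-12, 0.54 with an estimated correlation). Bipolar cells (-0.76, adjusted p = 2.2e-04, 0.66 with an estimated correlation), retinal ganglion cells (-0.59, adjusted p = 4.8e-04, 0.64) and oligodendrocytes and optic nerve (-1.07, adjusted p = 0.001, 0.64) were lower too. The oxidative stress list (-0.49, adjusted p = 0.013, 0.78 with an estimated correlation) did not pass without poke DMSO replicate 3 (-0.22).

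Rises with PLX3397 were led by tfa, which encodes transferrin (0.292 ± 0.388 to 14.4 ± 4.72 CPM, 5.45, adjusted p = 7.8e-04, or 7.61 without poke DMSO replicate 1), and tmem116, a membrane protein gene (3.01 ± 0.501 to 33.6 ± 5.05, 3.48, adjusted p = 1.1e-06). The Müller glia identity list had a median of 0.11 and did not pass (adjusted p = 0.59).

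ZVAD-fmk against DMSO after poke asks the same for caspase inhibition. With edgeR, 2069 genes were higher and 1912 lower, 3981 in all, and the total was 2377, 2378 and 2385 without ZVAD-fmk replicate 1, 2 and 3, and 6164 without the 4 libraries that stand apart. Genes of dividing cells were again lower. The mitotic kinase gene aurka fell from 19 ± 1.87 to 1.01 ± 0.543 CPM (-4.22, adjusted p = 2.1e-05, or -4.82 without the 4 libraries that stand apart) and mki67 from 218 ± 18.2 to 22.1 ± 2.51 (-3.30, adjusted p = 3.3e-08). Of 87 mitosis and cytokinesis genes, 0 rose, 83 fell and 4 were not called (1 and 85 adjusted over the list alone), with a median of -2.87 (adjusted p = 1.2e-159, 2.9e-04 with an estimated correlation). Of 71 DNA replication genes, 0 rose, 45 fell and 26 were not called (0 and 53 adjusted over the list alone), with a median of -0.82 (adjusted p = 1.7e-24, 0.33 with an estimated correlation). Of 36 proneural and neurogenic genes, 1 rose, 19 fell and 16 were not called (1 and 22 adjusted over the list alone), with a median of -0.88 (adjusted p = 1.7e-11, 0.0013 with an estimated correlation). Here foxn4 fell from 42.1 ± 4.35 to 6.81 ± 0.35 CPM (-2.63, adjusted p = 6.8e-07).

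Photoreceptor genes were lower with ZVAD-fmk. Of 34 cone genes, 0 rose, 25 fell and 9 were not called (0 and 28 adjusted over the list alone), with a median of -1.29 (adjusted p = 9.3e-35, 0.053 with an estimated correlation). The red cone opsin gene opn1lw2 fell from 434 ± 55.1 to 32.9 ± 5.31 CPM (-3.72, adjusted p = 9.6e-08). Of 29 rod genes, 0 rose, 23 fell and 6 were not called (0 and 26 adjusted over the list alone), with a median of -1.39 (adjusted p = 2.3e-22, 0.12 with an estimated correlation). Bipolar cell genes had a median of -0.56 (adjusted p = 1.4e-04, 0.93 with an estimated correlation). Complement passed in the upward direction, with 6 of 22 genes higher and 2 lower (8 and 4 adjusted over the list alone) and a median of 0.50 (adjusted p = 0.032, 0.94 with an estimated correlation). It did not pass without poke DMSO replicate 1 (0.34) or 2 (0.17). Within it, c7b rose from 2360 ± 491 to 8750 ± 845 CPM (1.89, adjusted p = 4.6e-04). The microglia and macrophage list had a median of -1.03 (11 of 62 genes lower, 2 higher, adjusted p = 0.016, 0.94 with an estimated correlation), but without poke DMSO replicate 3 it was 0.16 (adjusted p = 0.99). The same library decided the pigment epithelium and melanophore list (-0.81, adjusted p = 0.033, 0.93 with an estimated correlation, and -0.47 without it). The retinal ganglion cell list (-0.27, adjusted p = 0.031, 0.94 with an estimated correlation) did not pass without poke DMSO replicate 1 (-0.28) or 2 (-0.21).

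**Figure D3:**
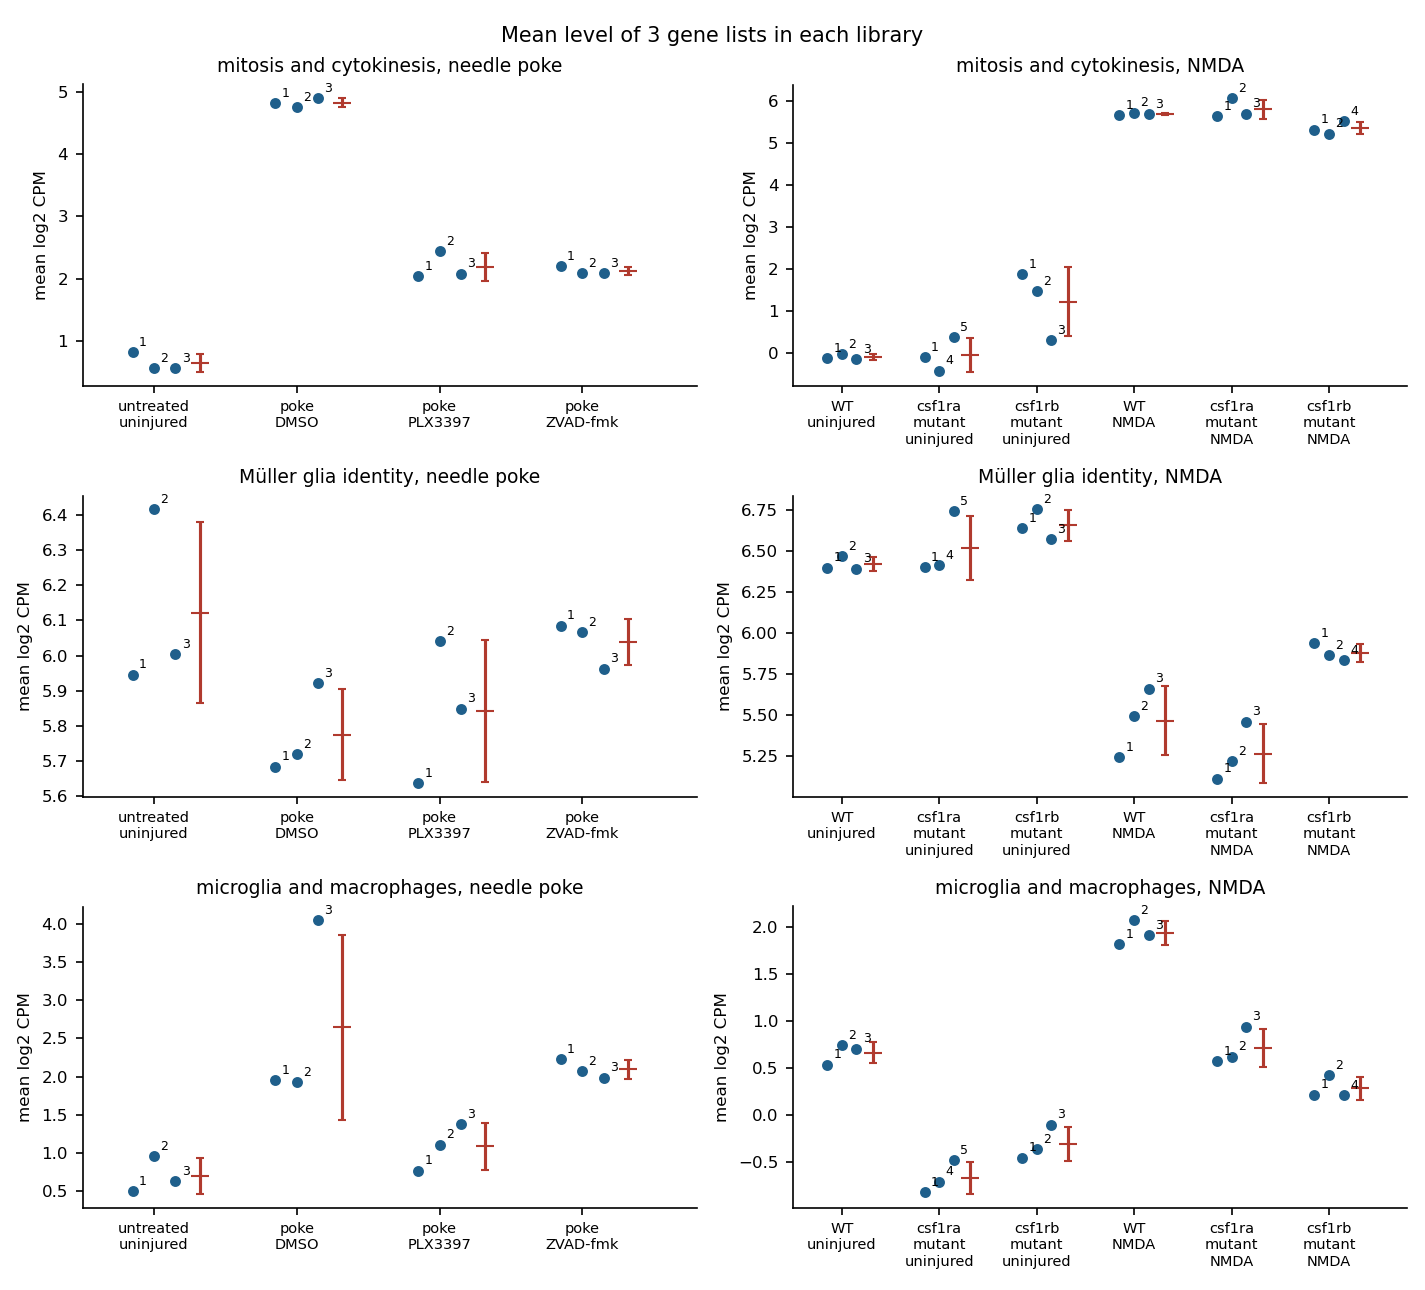
Mean level (vertical axis, log2 CPM) of the mitosis, Müller glia and microglia lists in each library, by group, for both experiments. Points are libraries with their replicate number, and bars are the mean and SD. All 3 poke DMSO libraries lie above the PLX3397 and ZVAD-fmk libraries in the mitosis list, and poke DMSO replicate 3 lies at 4.05 in the microglia list.

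PLX3397 against ZVAD-fmk after poke asks where the drugs differ. Of 21334 genes, edgeR called 732 higher and 1026 lower with PLX3397, 1758 in all, which changed with the libraries used. The total was 284, 338 and 415 without ZVAD-fmk replicate 2, 1 and 3, 497, 786 and 2635 without PLX3397 replicate 3, 1 and 2, and 5708 without the 4 libraries that stand apart, and DESeq2 gave 3002. The sterol synthesis list was higher with PLX3397. Lanosterol synthase, lss, was at 10.8 ± 3.32 CPM against 2.86 ± 0.328 (1.92, adjusted p = 0.0024), and 5 of 27 genes of the cholesterol list were higher and 0 lower (11 and 0 adjusted over the list alone, median 0.54, adjusted p = 5.0e-07, 0.83 with an estimated correlation). Of 34 cone genes, 7 were higher, 0 lower and 27 not called (9 and 0 adjusted over the list alone), among them the green opsin gene opn1mw2, higher at 313 ± 99.1 against 75.5 ± 18.2 CPM (2.05, adjusted p = 0.0018, list median 0.38, adjusted p = 2.4e-06, 0.83 with an estimated correlation). The microglia and macrophage list was lower (median -1.20, 1 of 62 genes higher and 3 lower, adjusted p = 1.2e-06, 0.83 with an estimated correlation). Lower medians passed for oligodendrocytes and optic nerve (-0.81, adjusted p = 0.0046), retinal ganglion cells (-0.40, adjusted p = 0.013), injury-associated reprogramming (-0.21, 4 of 64 lower and 1 higher, adjusted p = 0.014), oxidative stress (-0.23, adjusted p = 0.02) and glycolysis and hypoxia (-0.22, adjusted p = 0.036), each at 0.83 with an estimated correlation. The last 3 did not pass without PLX3397 replicate 1 (-0.14, -0.21 and -0.15) or 3 (-0.14, -0.26 and -0.18). Without ZVAD-fmk replicate 1, oxidative stress (-0.19) and glycolysis (-0.13) did not pass, and without PLX3397 replicate 2 (-0.13) or the 4 libraries that stand apart (-0.23) ganglion cells did not. The mitosis list did not differ detectably (0.15, adjusted p = 0.41).

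Agreement of the drugs was measured over the 21334 genes. The log2 fold changes of PLX3397 and ZVAD-fmk, both against the same DMSO libraries, had r = 0.79 and a covariance of 0.926. Unchanged groups simulated against shared controls gave r = 0.501 and a covariance of 0.201, which leaves 0.725. Calls in both were 1659 higher (340.5 if independent) and 1520 lower (339.3), and 2 genes were called in opposite directions. Part of that excess may come from the shared controls.

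**Figure D4:**
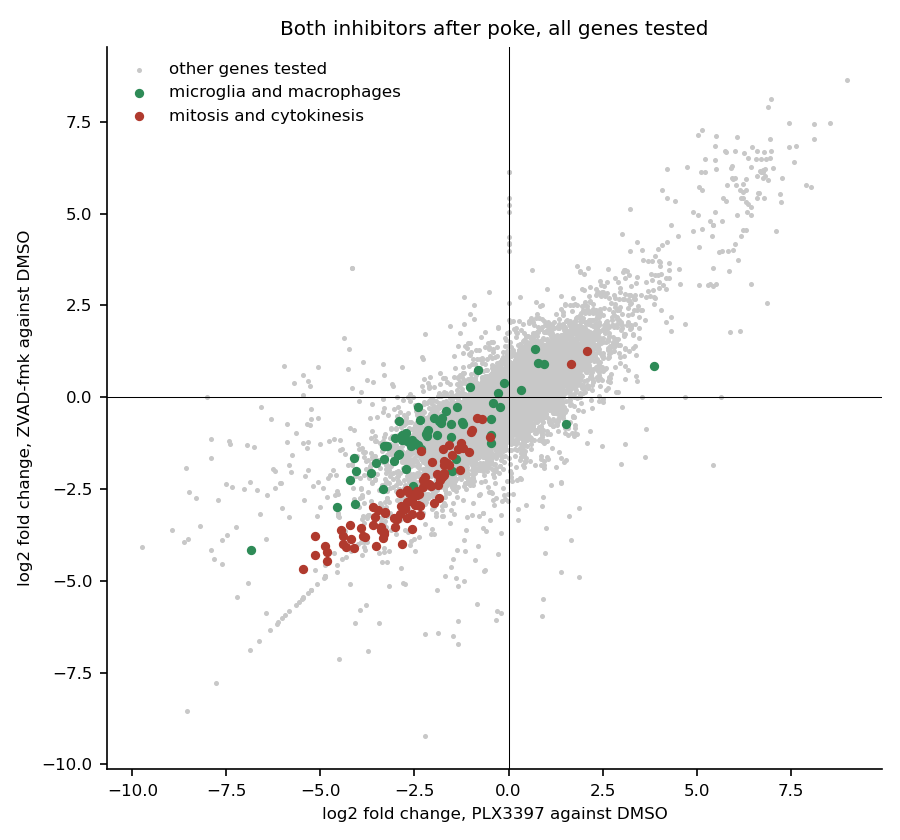
Log2 fold change with PLX3397 (horizontal axis) and with ZVAD-fmk (vertical axis), each against poke DMSO, for the 21334 genes tested. Red points are mitosis and cytokinesis genes, green points microglia and macrophage genes and grey points all others. Most red points lie low on both axes, with medians of -2.57 and -2.87.

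NMDA against uninjured retinas in wild type cannot separate effects of NMDA from those of injection. Of 20254 genes, edgeR called 7210 higher and 6939 lower after NMDA. All 70 DNA replication genes rose (70 adjusted over the list alone), with a median of 4.84 (adjusted p = 1.9e-91, 0.0047 with an estimated correlation). Of 87 mitosis and cytokinesis genes, 84 rose and 3 fell (84 and 3 adjusted over the list alone), with a median of 6.54 (adjusted p = 1.2e-51, 0.22 with an estimated correlation). The maintenance methyltransferase gene dnmt1 went from 20.2 ± 0.407 to 243 ± 3.2 CPM (3.59, adjusted p = 2.6e-14). The largest rises were in stm (1760 ± 797 against 0.0126 ± 0.0218 CPM, 1 count over the uninjured group, adjusted p = 4.7e-12), which encodes an otolith matrix protein, and clcf1 (171 ± 30.8 against 0.026 ± 0.0226 CPM, 2 counts, adjusted p = 8.2e-13). The protease gene mmp9 rose from 1.73 ± 0.415 to 3830 ± 1040 CPM (2200-fold, adjusted p = 3.4e-13). Of 62 injury-associated reprogramming genes, 35 rose, 13 fell and 14 were not called (35 and 13 adjusted over the list alone), with a median of 1.24 (adjusted p = 3.1e-06, 0.27 with an estimated correlation). Immune lists were higher too. Microglia and macrophages had a median of 1.34 (37 of 57 higher, 7 lower, adjusted p = 0.016, 0.51 with an estimated correlation), interferon response 1.09 (adjusted p = 0.015, 0.51), inflammation 1.45, or 1.39 with bounds (adjusted p = 0.023, 0.51), and neutrophils 1.98 (adjusted p = 0.046, 0.51). The last did not pass in 5 other settings, such as without wild-type uninjured replicate 2 (1.89).

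Neuronal and glial genes were lower after NMDA in wild type. Of 25 amacrine genes, 0 rose, 23 fell and 2 were not called (0 and 24 adjusted over the list alone), with a median of -1.62 (adjusted p = 1.4e-05, 0.51 with an estimated correlation). Choline acetyltransferase, CHAT, which marks starburst amacrine cells, fell from 167 ± 10.4 to 16.8 ± 5.08 CPM (-3.32, adjusted p = 4.4e-09). Of 44 Müller glia identity genes, 8 rose, 26 fell and 10 were not called (8 and 26 adjusted over the list alone), with a median of -1.25 (adjusted p = 1.3e-04, 0.51 with an estimated correlation). The potassium channel gene KCNJ10 (ENSDARG00000105022) fell from 28.3 ± 2 to 1.25 ± 0.464 CPM (-4.51, adjusted p = 7.2e-11). The ganglion cell factor gene pou4f2 fell (-4.04, adjusted p = 4.8e-08), while the growth cone gene gap43 of the same list rose from 7.21 ± 0.427 to 282 ± 48.9 CPM (5.29, adjusted p = 1.3e-08). Lower medians passed for bipolar cells (-1.39, adjusted p = 8.7e-05), rods (-1.73, adjusted p = 1.8e-04), cones (-1.23, adjusted p = 0.0042), retinal ganglion cells (-1.27, adjusted p = 0.0042) and horizontal cells (-1.71, adjusted p = 0.0081), each at 0.51 with an estimated correlation. So did cholesterol synthesis (-1.70, adjusted p = 0.0053, 0.56 with an estimated correlation), heat shock (-0.63, adjusted p = 0.008, 0.57), the circadian clock (-0.70, adjusted p = 0.015, 0.51) and glycolysis and hypoxia (-0.62, adjusted p = 0.042, 0.51). The glycolysis list did not pass without wild-type NMDA replicate 3 (-0.64) or wild-type uninjured replicate 2 (-0.55).

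NMDA against uninjured retinas within each mutant asks whether the same changes occur there. In csf1ra mutants, edgeR called 7367 genes higher and 7514 lower, and in csf1rb mutants 7488 higher and 6791 lower. All 70 DNA replication genes rose in both (70 adjusted over the list alone in each), with medians of 4.51 (adjusted p = 9.4e-73, 0.015 with an estimated correlation) and 4.19 (adjusted p = 9.5e-73, 0.011). Of 87 mitosis genes, 84 rose and 3 fell in both (84 and 3 adjusted over the list alone), with medians of 6.52 in csf1ra mutants (adjusted p = 6.7e-44, 0.24 with an estimated correlation) and 4.4 in csf1rb mutants (adjusted p = 1.2e-33, 0.29). The replicative polymerase gene pold1 rose from 5.5 ± 0.483 to 149 ± 14.3 CPM in csf1ra mutants (4.76, adjusted p = 1.8e-14) and from 7.96 ± 0.527 to 144 ± 10 in csf1rb mutants (4.18, adjusted p = 1.1e-13). The p53 and apoptosis list passed with medians of 0.72 (adjusted p = 0.0084, 0.45 with an estimated correlation) and 0.78 (adjusted p = 0.013, 0.61), against 0.51 in wild type (adjusted p = 0.055). The difference from wild type itself passed for csf1ra mutants (0.27, adjusted p = 0.0048, 0.5 with an estimated correlation) but not for csf1rb mutants (0.17, adjusted p = 0.13). The largest fall in csf1ra mutants was in cndp1, a dipeptidase gene, from 12.5 ± 5 CPM to no counts (at least 357-fold lower, adjusted p = 2.1e-04). In csf1rb mutants the serine protease gene hpn went from no counts to 14.2 ± 1.88 CPM (at least 410-fold higher, adjusted p = 2.3e-11). Microglia and macrophages passed in csf1ra mutants (median 2.07, adjusted p = 0.034, 0.45 with an estimated correlation), but not without csf1ra mutant NMDA replicate 3 (2.16) or uninjured replicate 5 (2.46). They did not pass in csf1rb mutants (0.64, adjusted p = 0.49), and the difference between the mutants was not tested. Other lists passed in both mutants (medians in csf1ra and csf1rb mutants, adjusted p 0.043 or less). Higher were reprogramming (1.55 and 1.26), inflammation (2.23 and 1.87) and interferon response (1.70 and 1.47). Lower were amacrine (-2.07 and -2.43), bipolar (-2.34 and -1.87), rod (-2.25 and -1.08), cone (-1.70 and -1.34), ganglion cell (-1.61 and -1.51), Müller glia (-1.73 and -0.90), oligodendrocyte (-1.24 and -1.34), cholesterol (-2.29 and -2.62), circadian (-1.11 and -0.84) and xenobiotic (-0.61 and -0.77) lists. The Notch pathway (0.71) and glycolysis (-0.84) passed in csf1ra mutants and oxidative stress (0.97) in csf1rb mutants. None passed with an estimated correlation. Single libraries ended the calls of Notch (uninjured replicate 5, 0.62), circadian (NMDA replicate 2, -0.93), glycolysis (NMDA 3, -0.90) and oligodendrocytes (NMDA 1, -1.06) in csf1ra mutants, and of circadian (NMDA 4, -0.82, uninjured 3, -0.74) and oligodendrocytes (NMDA 4, -1.25) in csf1rb mutants.

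Responses to the 2 kinds of injury share no library and were compared directly. Over 19920 genes the log2 fold changes after poke and after NMDA in wild type had r = 0.721. Calls in both were 3479 higher (1353.6 if independent) and 2198 lower (952.4), and 94 genes were called in opposite directions. Genes called higher after NMDA were higher after poke as a set of 7118 (median 0.55, 87.1% above 0, camera adjusted p = 3.0e-55, 0.015 with an estimated correlation). The same set had a median of -0.26 with PLX3397 (34.2% above 0, adjusted p = 1.8e-07, 0.41 with an estimated correlation) and of -0.05 with ZVAD-fmk (adjusted p = 0.25). The set lower after NMDA had a median of 0.18 with PLX3397 (adjusted p = 0.0016, 0.5 with an estimated correlation) and of -0.03 with ZVAD-fmk (adjusted p = 0.72). These tests changed with the libraries. The lower set lost its call with PLX3397 without poke PLX3397 replicate 1 (adjusted p = 0.14). With ZVAD-fmk the higher set passed without poke DMSO replicate 2 (adjusted p = 0.042), and the lower set without poke DMSO replicate 3 (0.032) and without the 4 libraries that stand apart (0.036). For the 200 genes with the smallest p among those higher after NMDA, the medians were -0.74 with PLX3397 (adjusted p = 1.8e-18, 0.23 with an estimated correlation) and -0.65 with ZVAD-fmk (adjusted p = 6.6e-20, 0.23).

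csf1ra mutants against wild type after NMDA compare lines of unknown background that also differed uninjured. Of 20254 genes, edgeR called 1871 higher and 2665 lower in the mutants. Of 57 microglia and macrophage genes, 1 was higher, 35 lower and 21 not called (1 and 36 adjusted over the list alone), with a median of -1.41 (adjusted p = 1.1e-15, 0.029 with an estimated correlation). The leukocyte actin regulator coro1a was at 1.74 ± 0.461 CPM against 7.52 ± 1.1 (-2.11, adjusted p = 1.0e-05). Bipolar genes had a median of -1.13, with 17 of 24 lower (18 adjusted over the list alone, adjusted p = 2.1e-10, 0.2 with an estimated correlation), and the channel gene trpm1b of ON bipolar cells was at 17 ± 2.83 against 41.7 ± 7.41 CPM (-1.30, adjusted p = 2.8e-05). Rods (-1.26, 25 of 29 lower, adjusted p = 2.9e-10, 0.47 with an estimated correlation), cones (-0.78, adjusted p = 8.0e-06, 0.47) and complement (-0.90, adjusted p = 2.1e-04, 0.2) were lower too. So was the endothelium and mural cell list (-0.44, 9 of 28 lower and 1 higher, adjusted p = 0.049, 0.47 with an estimated correlation), but not without wild-type NMDA replicate 1 (-0.64) or 3 (-0.38) or csf1ra mutant NMDA replicate 1 (-0.42) or 2 (-0.36). The mitosis list (0.15, adjusted p = 0.17) and the DNA replication list (-0.02, adjusted p = 0.79) did not differ detectably.

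Higher in injured csf1ra mutants were reprogramming genes, with 17 of 62 higher and 2 lower (21 and 3 adjusted over the list alone, median 0.31, adjusted p = 3.2e-04, 0.44 with an estimated correlation). The annexin gene ANXA2 was at 163 ± 34.8 against 12.7 ± 2.4 CPM (3.68, adjusted p = 1.0e-07). Small positive medians passed for p53 and apoptosis (0.31, adjusted p = 1.1e-04, 0.44 with an estimated correlation), heat shock (0.53, adjusted p = 0.0045, 0.75), the Notch pathway (0.31, adjusted p = 0.0058, 0.47) and oxidative stress (0.31, adjusted p = 0.0058, 0.47). Inflammation also passed (0.63, adjusted p = 0.0058, 0.47 with an estimated correlation), but not without csf1ra mutant NMDA replicate 3 (0.45). Cholesterol synthesis (0.39, adjusted p = 0.03, 0.75 with an estimated correlation) did not pass without replicate 1 of either group (0.34 and 0.33). Interferon response (0.33, adjusted p = 0.046, 0.57) did not pass without wild-type NMDA replicate 1 (0.26) or 3 (0.16) or csf1ra mutant NMDA replicate 2 (0.30) or 3 (0.34). The Notch target her4.4 was at 505 ± 31.7 against 102 ± 41.5 CPM (2.31, adjusted p = 1.6e-05) and its near-identical neighbour in sequence her4.3 at 1.8 ± 0.305 against 29.4 ± 15.9 (-4.02, adjusted p = 1.6e-05), so the split between these copies is uncertain. The largest rise was in f10, coagulation factor X (5.28 ± 0.355 against 0.0223 ± 0.0387 CPM, 2 counts in wild type, adjusted p = 7.9e-07), and the largest fall in tnfrsf14, a receptor of the TNF family (0.0704 ± 0.0358 against 7.73 ± 0.504 CPM, -6.70, adjusted p = 2.2e-08).

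csf1rb mutants against wild type after NMDA do the same for the paralog. With edgeR, 2402 genes were higher and 2304 lower in the mutants. Of 57 microglia and macrophage genes, 3 were higher, 41 lower and 13 not called (3 and 45 adjusted over the list alone), with a median of -1.85 (adjusted p = 3.2e-24, 0.0061 with an estimated correlation). The leukocyte plastin gene lcp1 was at 0.55 ± 0.229 against 9.38 ± 2 CPM (-4.03, adjusted p = 1.6e-07) and the complement gene c1qb at 0.0804 ± 0.0133 against 3.08 ± 0.678 (-5.15, adjusted p = 2.1e-05). The rod list was lower in 24 of 29 genes (24 adjusted over the list alone, median -1.55, adjusted p = 2.0e-14, 0.36 with an estimated correlation), as was the cone list in 24 of 34 (25 adjusted over the list alone, median -1.47, adjusted p = 4.5e-14, 0.36). Bipolar cells were at -0.96 (adjusted p = 6.5e-07, 0.36 with an estimated correlation) and complement at -0.73 (adjusted p = 0.0019, 0.36). Cell-cycle lists were slightly lower, with 9 of 87 mitosis genes lower and 0 higher (median -0.31, adjusted p = 0.0017, 0.59 with an estimated correlation) and 7 of 70 DNA replication genes lower (-0.22, adjusted p = 0.0034, 0.52). The cyclin gene ccnb3 was at 8.41 ± 0.565 against 14.3 ± 0.31 CPM (-0.77, adjusted p = 0.0026).

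Müller glia identity genes were higher in injured csf1rb mutants, 20 of 44 against 5 lower (21 and 6 adjusted over the list alone, median 0.51, adjusted p = 9.9e-04, 0.48 with an estimated correlation). Glutamine synthetase, GLUL (ENSDARG00000099776), was at 2240 ± 78.9 against 711 ± 193 CPM (1.66, adjusted p = 9.4e-06) and KCNJ10 (ENSDARG00000105022) at 6.04 ± 1.18 against 1.25 ± 0.464 (2.27, adjusted p = 7.5e-06). The glucose transporter gene SLC2A1 (ENSDARG00000001437) was at 213 ± 20.9 against 43.5 ± 16.1 CPM (2.29, adjusted p = 2.9e-06), in a glycolysis list with a median of 0.33 (adjusted p = 0.016, 0.48 with an estimated correlation). Oligodendrocytes and optic nerve had a median of 0.52 (adjusted p = 0.0034, 0.43 with an estimated correlation), with sox10, a factor of that lineage, at 26 ± 0.661 against 10.2 ± 2.77 CPM (1.36, adjusted p = 1.7e-04). The Notch pathway was at 0.43 (adjusted p = 0.0041, 0.48 with an estimated correlation). Other medians that passed were p53 and apoptosis (0.21, adjusted p = 0.0074), ganglion cells (0.45, adjusted p = 0.0074), interferon response (-0.30, adjusted p = 0.015), amacrine cells (-0.48, adjusted p = 0.021), heat shock (0.51, adjusted p = 0.022), xenobiotic response (0.50, adjusted p = 0.027), oxidative stress (0.20, adjusted p = 0.035) and extracellular matrix (0.50, adjusted p = 0.037), at 0.48 to 0.59 with an estimated correlation. Of these only p53 passed without each of the 6 libraries. Without csf1rb mutant NMDA replicate 4, amacrine cells (-0.27), heat shock (0.33), xenobiotic response (0.42) and oxidative stress (0.13) did not pass, and without replicate 2 ganglion cells did not (0.32). Without wild-type NMDA replicate 1, heat shock (0.36), xenobiotic response (0.35), oxidative stress (0.10) and matrix (0.43) did not, and without replicate 2 matrix (0.49) and interferon (-0.13) did not. As in csf1ra mutants, f10 had the largest rise (9.26 ± 0.729 against 0.0223 ± 0.0387 CPM, adjusted p = 9.2e-08). The lectin gene lgals3bp.1 of the microglia list had the largest fall under the rule for named genes (1.56 ± 0.444 against 45.6 ± 14.1, -4.86, adjusted p = 7.6e-09), and stm was at 72.5 ± 5.7 against 1760 ± 797 CPM (-4.60, adjusted p = 4.0e-07).

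Both mutants shared the wild-type NMDA libraries as their control. Their log2 fold changes had r = 0.712 and a covariance of 0.614, against 0.492 and 0.059 in simulated unchanged groups, which leaves 0.555. Calls in both were 899 higher (221.9 if independent) and 1356 lower (303.2), with 82 in opposite directions, and part of the excess may come from the shared controls.

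Uninjured csf1ra mutants against uninjured wild type give the differences before injury. With edgeR, 1609 genes were higher and 1366 lower, 2975 in all, a total that was 1653 without wild-type uninjured replicate 1, 1603 without replicate 3 and 1537 with only these groups in the fit. Of 57 microglia and macrophage genes, 0 were higher, 34 lower and 23 not called (2 and 36 adjusted over the list alone), with a median of -1.82, or -1.68 with bounds (adjusted p = 6.4e-19, 0.016 with an estimated correlation). The antigen presentation gene cd74a was at 1.23 ± 0.419 against 11.4 ± 0.685 CPM (-3.20, adjusted p = 6.4e-06). The largest rise was in f10 (15.9 ± 8.09 against 0.114 ± 0.0603 CPM, 7.06, adjusted p = 9.5e-08) and the largest falls were in otoa, an inner ear matrix gene (0.0117 ± 0.0202 against 13.6 ± 2.91, 1 count in the mutants, adjusted p = 3.7e-07), and tnfrsf14 (0.3 ± 0.195 against 21.8 ± 2.45, -6.17, adjusted p = 4.8e-09, and from -7.06 to -5.81 in other settings). Rod genes were lower in 13 of 29 (median -0.76, adjusted p = 2.8e-06, 0.86 with an estimated correlation), and oligodendrocyte genes higher in 8 of 16 (0.82, adjusted p = 3.1e-04, 0.71). Other lists depended on single libraries, 3 of them on csf1ra mutant uninjured replicate 5. Cholesterol synthesis (0.81, adjusted p = 0.014, 0.87 with an estimated correlation) was at -0.11 without it (adjusted p = 0.71), and neither retinal ganglion cells (0.55, adjusted p = 0.014, 0.86, and 0.28 without it) nor heat shock (-0.40, adjusted p = 0.002, 0.86, and -0.33 without it) passed. Ganglion cells did not pass without wild-type uninjured replicate 2 (0.44) either. Pigment epithelium and melanophores (-0.58, 1 of 19 lower and 0 higher, adjusted p = 0.029, 0.86 with an estimated correlation) did not pass without that library (-0.76) or csf1ra mutant uninjured replicate 1 (-0.69) or 4 (-0.47).

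Uninjured csf1rb mutants against uninjured wild type differed in more genes, with 2931 higher and 2514 lower by edgeR. Genes of dividing cells were higher without injury. Of 87 mitosis and cytokinesis genes, 56 were higher, 0 lower and 31 not called (66 and 0 adjusted over the list alone), with a median of 1.64 (adjusted p = 1.5e-17, 0.52 with an estimated correlation). The libraries of the mutants differed, with list means of 1.89, 1.49 and 0.31 log2 CPM in replicates 1, 2 and 3 against -0.12, -0.01 and -0.14 in wild type. The median without csf1rb mutant uninjured replicate 1 was 1.17, still past the test. In these retinas mki67 was at 15.2 ± 10.2 against 2.15 ± 0.468 CPM (2.81, adjusted p = 1.4e-04). DNA replication genes had a median of 0.50 (36 of 70 higher, 2 lower, adjusted p = 3.7e-08, 0.52 with an estimated correlation) and proneural genes of 0.75 (adjusted p = 0.0053, 0.52). The latter did not pass without csf1rb mutant uninjured replicate 1 (0.71). Among them tubb5 was higher (2.85, adjusted p = 2.4e-07).

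Photoreceptor genes were lower in uninjured csf1rb mutants. Of 29 rod genes, 1 was higher, 27 lower and 1 not called (1 and 27 adjusted over the list alone), with a median of -2.16 (adjusted p = 9.4e-23, 0.25 with an estimated correlation), and gnat1 was at 326 ± 114 against 2600 ± 247 CPM (-2.99, adjusted p = 1.5e-05). Of 34 cone genes, 2 were higher and 24 lower (2 and 24 adjusted over the list alone), with a median of -1.17 (adjusted p = 1.4e-12, 0.31 with an estimated correlation). Microglia and macrophages were lower in 30 of 57 genes and higher in 2 (2 and 32 adjusted over the list alone, median -1.08, adjusted p = 6.0e-09, 0.24 with an estimated correlation), with the lysosomal gene hexb at 43.7 ± 2.83 against 92.1 ± 10.4 CPM (-1.08, adjusted p = 6.0e-06). Higher medians passed for oligodendrocytes (1.23, or 1.17 with bounds, adjusted p = 2.0e-05, 0.29 with an estimated correlation), retinal ganglion cells (0.70, adjusted p = 4.8e-05, 0.54), cholesterol synthesis (1.21, adjusted p = 2.3e-04, 0.63), xenobiotic response (0.50, adjusted p = 0.0018, 0.31) and extracellular matrix (0.63, adjusted p = 0.028, 0.63). The matrix list did not pass without csf1rb mutant uninjured replicate 3 (0.46) or wild-type uninjured replicate 2 (0.49). Interferon response genes were lower (-0.44, adjusted p = 5.6e-04, 0.45 with an estimated correlation), with b2m, a chain of MHC class I, at 13.1 ± 3.82 against 52.1 ± 2.83 CPM (-1.99, adjusted p = 1.2e-06). Bipolar cells (-0.31, 7 of 24 lower and 2 higher, adjusted p = 0.0053, 0.63 with an estimated correlation) and heat shock (-0.16, 13 of 47 lower and 4 higher, adjusted p = 0.0036, 0.73) were lower too. The heat shock list did not pass without csf1rb mutant uninjured replicate 1 (-0.02).

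Interactions test whether the NMDA change of a mutant differs from that of the wild type. For csf1ra, 518 genes had a more positive and 663 a more negative change in the mutants, and 1181 were called in all. That total was 598 without csf1ra mutant NMDA replicate 1, 680 without wild-type NMDA replicate 2, and 681 and 622 without wild-type uninjured replicates 1 and 3, and DESeq2 gave 1898. The receptor gene csf1ra itself rose more in csf1ra mutants than in wild type (interaction 1.72, adjusted p = 0.0096). The cell cycle inhibitor gene cdkn1a rose from 11.9 ± 2.6 to 104 ± 11.4 CPM in csf1ra mutants and from 52.3 ± 15.4 to 74.6 ± 3.59 in wild type (interaction 2.62, adjusted p = 2.2e-04). The matrix gene abi3bpb went from 93.8 ± 12.7 to 17.9 ± 8.36 CPM in the mutants and from 301 ± 43.8 to 0.992 ± 0.479 in wild type (5.85, adjusted p = 3.1e-04). Bipolar genes changed more negatively in 10 of 24 (15 adjusted over the list alone, median -1.09, adjusted p = 5.2e-09, 0.5 with an estimated correlation). The microglia and macrophage list did not differ detectably (0.52, adjusted p = 0.052), nor did the mitosis list (0.12, adjusted p = 0.48).

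For csf1rb, 831 genes had a more positive and 825 a more negative NMDA change in the mutants, 1656 in all. That total was 1045 without csf1rb mutant NMDA replicate 1, 1055 and 1026 without csf1rb mutant uninjured replicates 1 and 2, 1101 without wild-type NMDA replicate 2, 1088, 1027 and 984 without wild-type uninjured replicates 1, 2 and 3, and 2686 with only these groups in the fit. Of 87 mitosis and cytokinesis genes, 0 had a more positive and 52 a more negative change, and 35 were not called (0 and 74 adjusted over the list alone, median -2, adjusted p = 9.4e-40, 0.34 with an estimated correlation). Most of that difference lay before injury, when the list was higher in the mutants (median 1.64). After NMDA it was only slightly below wild type. Of 70 DNA replication genes, 32 had a more negative change (39 adjusted over the list alone, median -0.71, adjusted p = 5.8e-21, 0.34 with an estimated correlation). The cyclin gene ccnb3 rose from 3.45 ± 1.05 to 8.41 ± 0.565 CPM in csf1rb mutants and from 0.413 ± 0.0715 to 14.3 ± 0.31 in wild type (interaction -3.81, adjusted p = 9.8e-07). The DNA replication gene e2f8 rose from 1.49 ± 0.401 to 45.6 ± 0.62 and from 0.336 ± 0.163 to 58.3 ± 5.85 CPM (-2.48, adjusted p = 2.8e-04). Genes higher after poke, cell-cycle genes included, were tested in the interaction as a set of 3788 from the other experiment. Their median was -0.14 (adjusted p = 0.0067, 0.51 with an estimated correlation) in csf1rb mutants and 0.06 (adjusted p = 1.2e-04, 0.45) in csf1ra mutants. The csf1rb value lost its call without csf1rb mutant NMDA replicate 2 (adjusted p = 0.077).

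csf1ra mutants against csf1rb mutants after NMDA compare lines of unknown background, not paralogs. Of 20254 genes, edgeR called 1124 higher and 1916 lower in csf1ra mutants, 3040 in all, whereas RLE factors gave 1614 and 1608. The total was 1937 without csf1ra mutant NMDA replicate 2 and 1782 and 1966 without csf1rb mutant NMDA replicates 1 and 2. Müller glia identity genes were lower in csf1ra mutants, 23 of 44 against 2 higher (2 and 26 adjusted over the list alone, median -0.70, adjusted p = 1.9e-08, 0.26 with an estimated correlation). In that list KCNJ10 (ENSDARG00000105022) was at 0.923 ± 0.00822 against 6.04 ± 1.18 CPM (-2.70, adjusted p = 4.8e-06). Interferon response genes were higher (12 of 45, 1 lower, 21 and 1 adjusted over the list alone, median 0.68, adjusted p = 6.9e-08, 0.17 with an estimated correlation), with b2m at 191 ± 11.4 against 67.4 ± 4 CPM (1.5, adjusted p = 3.3e-05). The largest rises were in parp9 of that list (4.05 ± 1.86 against 0.0433 ± 0.0556 CPM, 6.46, adjusted p = 3.3e-06, or 7.74 without csf1rb mutant NMDA replicate 4) and stm (3320 ± 523 against 72.5 ± 5.7 CPM, 5.52, adjusted p = 2.9e-07). The largest fall was in cldn7a, a claudin gene (1.07 ± 0.103 against 18.1 ± 5.78, -4.06, adjusted p = 7.9e-05). Mitosis (0.46, 13 of 87 higher, adjusted p = 1.9e-08, 0.65 with an estimated correlation), DNA replication (0.22, adjusted p = 9.7e-05, 0.65), microglia and macrophages (0.65, 12 of 57 higher and 6 lower, adjusted p = 0.0037, 0.6) and cones (0.43, adjusted p = 4.4e-04, 0.65) were higher. The microglia list did not pass with only these groups in the fit (0.55). Lower medians passed for glycolysis (-0.48, adjusted p = 5.9e-05, 0.21 with an estimated correlation), erythrocytes (-1.70, or -1.57 with bounds, adjusted p = 7.4e-05, 0.17), xenobiotic response (-0.63, adjusted p = 7.4e-05, 0.17) and the circadian clock (-0.44, adjusted p = 0.0046, 0.65). Inflammation (0.33, adjusted p = 0.038, 0.65) did not pass without csf1ra mutant replicate 3 (0.18) or csf1rb mutant replicate 2 (0.28), nor oligodendrocytes (-0.42, adjusted p = 0.046, 0.65) without csf1ra mutant replicate 1 or 3 or csf1rb mutant replicate 2 or 4 (-0.54 to -0.36).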

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

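The interaction tests were planned and the splits of the libraries were chosen after the results were seen. Of the tests on the patterns below, only the test of an injury response lower as a whole was chosen before, and all others were chosen after the result was seen.

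The NMDA change in csf1ra mutants differed from that in wild type in 1181 genes. Among the lists it was more positive for pigment epithelium and melanophores (median 1.79, from -0.58 against wild type before injury), immediate early and heat shock (0.89), horizontal cells (0.88), inflammation (0.39), interferon response (0.39), the Notch pathway (0.35) and p53 and apoptosis (0.27), and more negative for bipolar cells (-1.09), cones (-0.61) and Müller glia identity (-0.43). Adjusted p for these lists ran from 2.3e-10 (heat shock) to 0.028 (horizontal cells), and with an estimated correlation none passed (0.5 to 0.59). More positive genes were abi3bpb (5.85), HSPA8 ENSDARG00000037403 (4.97), ccnf (4.62), RPE65 ENSDARG00000007480 (3.96), si:busm1-57f23.1 (3.77), rnf213b (2.94), cdkn1a (2.62), nfkbiaa (2.21), tnfaip3 (2.11), csf1ra (1.72), her4.4 (1.44) and hsp70.1 (1.36). More negative genes were c7b (-3.32), clic5b (-3.10), mfng (-2.96), cav2 (-1.47), GNB3 (-1.45), aqp9b (-1.44), trpm1b (-1.27) and gfap (-1.21). Without csf1ra mutant uninjured replicate 5, c7b was at -1.89. Of 60 splits, 2 gave at least as many genes, the real one included (1181, highest other 1487, share 0.033). The splits shuffle genotypes within each state, so they ask whether genotype matters at all and not whether the injury change differs, and chance is not excluded as the source of the number. Leaving out 1 library gave 598 to 1613 genes.

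The NMDA change in csf1rb mutants differed in 1656 genes. It was more positive for erythrocytes (1.61), horizontal cells (1.35), pigment epithelium and melanophores (1.3), rods (0.57), heat shock (0.55), inflammation (0.47), Müller glia identity (0.14), oxidative stress (0.11) and glycolysis (0.08). It was more negative for mitosis and cytokinesis (-2), amacrine cells (-0.86), cholesterol synthesis (-0.85), complement (-0.80), DNA replication (-0.71), microglia (-0.62) and bipolar cells (-0.41). Adjusted p ran from 9.4e-40 (mitosis) to 0.04 (bipolar cells), and with an estimated correlation none passed (0.34 to 0.7). More positive genes were tnfrsf14 (5.86), abi3bpb (4.85), hspa1b (4.74), hbaa1 (3.43), tspan36 (1.78), ENO1 ENSDARG00000013750 (1.57), sqstm1 (1.40) and gnb1b (0.67). More negative genes were stm (-7.67), jac2 (-6.67), dscc1 (-5.62), ccnb3 (-3.81), lgals3bp.1 (-2.76), cfp (-2.52), e2f8 (-2.48), cenpw (-1.75) and NR4A2 ENSDARG00000044532 (-1.48). The values of stm and dscc1 rest on a group with 1 to 3 counts, as stm went from 0.152 ± 0.168 to 72.5 ± 5.7 CPM in csf1rb mutants and from 0.0126 ± 0.0218 to 1760 ± 797 in wild type, and dscc1 from 1.4 ± 0.186 to 23.3 ± 1.72 and from 0.0386 ± 0.00244 to a range of 34.6 to 35.9. The microglia list was at -0.03 without csf1rb mutant uninjured replicate 3. Of 60 splits, 4 gave at least as many genes, the real one included (1656, highest other 2310, share 0.067), so chance is not excluded as the source of the number, and these splits too do not test the interaction alone. Splits that reverse the genotypes in one state add the differences between genotypes to the interaction.

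For each of the 12 pairs of groups only 10 splits exist, too few for a share under 0.05, and in each the real one gave the most genes (1 of 10 splits). The real number and the highest other were 6744 and 1 for poke, 7297 and 0 for PLX3397, 3981 and 0 for ZVAD-fmk, and 1758 and 0 between the drugs. They were 14149 and 0 for NMDA in wild type, 14881 and 0 in csf1ra mutants, and 14279 and 0 in csf1rb mutants. Between genotypes they were 4536 and 1 and 4706 and 0 after NMDA, 2975 and 0 and 5445 and 0 uninjured (csf1ra and csf1rb mutants), and 3040 and 184 between the mutants.

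The egfp reporter, scaled to total gene counts without TMM factors, stood at 1035.4 ± 154.8 (range 865.3 to 1168) in uninjured csf1ra mutants and at 700 ± 103.5 (617.9 to 816.3) in uninjured wild type. The exact two-sided permutation p = 0.1 is the smallest possible with 3 against 3 libraries, so the test decides nothing and a difference stays open.

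Cell-cycle genes fell with both drugs after poke. Poke DMSO replicate 3 alone does not explain it, since without it the mitosis list was at -2.51 with PLX3397 and -2.79 with ZVAD-fmk. Glial RNA thinned by RNA of other cells would lower Müller glia genes too, and their medians were 0.11 and 0.12. An injury response lower as a whole was tested with 4241 other genes at least 2-fold higher after NMDA. Medians were -0.37 (SD 1.14, 347 higher and 1384 lower) and -0.08 (SD 1.01, 422 and 493). After poke, genes higher after NMDA had a median of 0.55 (mitosis 4.59), so the test cannot decide. Inhibition of the named targets stays open, as the 2 genes called in opposite directions decide nothing with shared DMSO libraries, and the drugs differed in 1758 genes.

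Both mutant lines shared called differences of at least 2-fold from wild type in 336 genes in both states (192 lower, 144 higher), 17 of them in the microglia list. Loss of receptor signalling could cause these, and the signed median of the shared genes with PLX3397 was 0.31, with 59.6% of 292 of the same sign. With ZVAD-fmk, which has another target, it was 0.26 (63.4%), so the drugs do not separate this from other causes. A difference in the genetic background of the lines was to be tested by the position of the genes, but only 57.4% had a position, so this too stays open.

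Cell-cycle genes were higher in uninjured csf1rb mutants. RNA of injured retinas mixed in (2.96% would be needed) would also raise other injury genes, and 26 of these had a median of 5.8% of the rise needed, 16 under 50% (mmp9 rose 0.382 of 150 CPM needed, ascl1a 0.132 of 15.8) and 10 not (hmga1a 77.5 of 28). A lower share of photoreceptor RNA would raise other cell types alike, but retinal ganglion cells (0.70, SD 0.82) and oligodendrocytes (1.23, SD 0.96) were higher while bipolar cells were at -0.31 (SD 0.72) and horizontal cells at -0.84 (SD 0.94), so it is not the whole cause, and a change in the types that rose stays open. The lowest median without 1 library was 1.17, so 1 library alone is not the cause. Loss of csf1rb might be, but stays open, since uninjured csf1ra mutants had a median of 0.05 and a single mutant line was measured.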

How the results depend on the processing

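Alternatives gave 294 other values for 19 results of comparisons and tests, of which 244 kept their label and 50 moved. For lists, 2364 of 2554 values stayed, 186 were weaker, 1 was stronger and 3 turned direction. For named genes, 4248 of 4360 stayed, 103 were weaker, 9 were stronger and 0 turned. The cause was not tested for any of these. Left-out fits keep 2 libraries in a group but the spread of all groups.

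With the correlation between genes estimated, 13 of 191 list tests and 4 of 13 tests of injury sets passed. Fry gave 199 and symbols alone, chosen after seeing the data, 155. Over genes of at least 10 CPM, r was 0.845 between the drugs (0.79 over all), 0.643 between the mutants (0.712) and 0.895 between the injuries (0.721).

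Leaving out 1 library gave 2377 to 3223 genes for ZVAD-fmk (3981), 284 to 2635 between the drugs (1758), 1603 to 4385 for uninjured csf1ra mutants (2975), 598 to 1613 and 984 to 1788 for the csf1ra and csf1rb interactions (1181 and 1656), and 1782 to 3007 between the mutants (3040). It gave r of 0.736 to 0.844 between the drugs, 0.668 to 0.736 between the mutants and 0.659 to 0.721 between the injuries. The microglia list with ZVAD-fmk (-1.03) ran from -1.43 to 0.16, turned without poke DMSO replicate 3 (adjusted p = 0.99). The cholesterol list of uninjured csf1ra mutants (0.81) ran from -0.11, turned without their replicate 5 (adjusted p = 0.71), to 1.1.

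Without the 4 libraries that stand apart, chosen after seeing the data, 6164 genes were called for ZVAD-fmk and 5708 between the drugs. DESeq2 gave 3002 between the drugs and 1898 for the csf1ra interaction. Only the groups compared gave 1537 for uninjured csf1ra mutants and 2686 for the csf1rb interaction.

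With a replicate block, 1630 genes were called for uninjured csf1ra mutants and 1897 for the csf1ra interaction, and the cholesterol list turned to -0.18 (adjusted p = 0.38). Libraries that share a number were not paired in the fits. Their 3 correlations were all over 0.1 for poke PLX3397 with untreated uninjured (0.165 to 0.552) and for wild-type uninjured with csf1ra mutant NMDA (0.108 to 0.412). Neither pair was compared directly, but the second enters the csf1ra interaction, so a pairing there is not excluded. No other pair of groups reached this.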

Other observations

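The egfp reporter, scaled as above, was at 860.57 ± 71.59 in untreated uninjured retinas. After poke it was at 410.7 ± 39.3, 391.8 ± 63.24 and 455.53 ± 21.08 with DMSO, PLX3397 and ZVAD-fmk. After NMDA it was at 274.2 ± 22.78 in wild type, 265.73 ± 48.64 in csf1ra mutants and 225.03 ± 5.54 in csf1rb mutants, and uninjured csf1rb mutants had 402.13 ± 42.38.

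The 200 genes with the smallest p among those higher after poke changed more negatively with NMDA in csf1rb mutants than in wild type (median -1.22, adjusted p = 4.8e-32, 0.072 with an estimated correlation). All 3788 gave -0.14 (adjusted p = 0.0067, 0.51 with an estimated correlation), and did not pass without csf1rb mutant NMDA replicate 2 (adjusted p = 0.077).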
